A study of Homo sapiens with 3 samples.

How the data were processed

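RNA sequencing was analysed in 3 libraries of the Ishikawa endometrial adenocarcinoma line, 2 with CLDN6 overexpression from a lentiviral vector and 1 untreated. Total RNA was isolated with TRIzol and libraries followed Illumina protocols, per the labels' protocols. The deposited table holds log2 values per gene, with 1 column per library and 35805 rows. The genome build was GRCh38, per the submitters' processing notes, and the aligner, the counter, the annotation release and the strand setting are not given in the sources used here. The column names carry the prefix ECC-1, which is in no label, while the labels name Ishikawa. Columns were matched to samples by the words CLDN6 1, CLDN6 2 and WT.

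The values were checked before use. In each library, 2 to the power of the deposited log2 value is a whole multiple of a single step for 99.9782%, 99.9275% and 99.9687% of values (tolerance 0.05 of a read) in CLDN6 replicate 1, CLDN6 replicate 2 and WT, so that the step is the worth of 1 read and the values are log2 of RPM, the reads of a gene per 1000000 reads. Genes without reads are listed at 0.9 of a read and were set to 0 reads. The steps give depths of 71088867, 65755119 and 67843384 reads, of which 68.1%, 68.1% and 68.2% lie in listed genes. The limit that 0 reads allow, taken as 3 reads, was 0.0422, 0.0456 and 0.0442 RPM. PCR copies are not independent molecules, so intervals and limits cover counting error only. The CLDN6 libraries differed by a chi-square of 602 per gene, so their reads are not those of a single library deposited again, and they were counted as separate libraries. This does not show separate cultures.

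Of the rows, 28 had names turned into dates, which were restored by gene ID, and 92 rows without a gene ID or with a shared gene ID and no read were left out. This left 35713 rows. Gene types, GC content and the length of the longest transcript came from GENCODE release 29, in which 34884 gene IDs were found. Of these, 91.4% had the same start and end as in the table. Coordinates are those of the table. A count per gene without a stated strand setting cannot part a gene from one that overlaps it, so such genes are named as uncertain.

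The choices below were fixed before the data were examined, apart from those named as added. The design fixed 1 test for counts and 1 for normalized values, and since the deposited values are on a log2 scale, the test for normalized values was used. Values were taken as log2(RPM + 1), genes with a mean of at least 1 RPM over the 3 libraries were kept (14509), and the CLDN6 libraries were compared with WT by limma 3.58.1 with a mean-variance trend in R 4.3.3. The fit has 1 residual degree of freedom, and the lone WT library is assumed to vary like the CLDN6 libraries. The prior degrees of freedom, by which limma shares the spread across genes, came out infinite, so p-values rest on that shared spread. p-values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Genes at least 2-fold from WT in both CLDN6 libraries, and between the CLDN6 libraries, were counted without a test. Each script was tested on simulated data. With an SD of 0.1 log2 units per library, the test called 100% of genes changed 2-fold, with 5 false calls among 14509 genes.

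Fixed in advance were 40 gene lists of pathways, complexes, library quality and cell types. The 35 with at least 5 genes tested were compared with the other genes by camera (limma) with a preset correlation of 0.01, and again with a correlation estimated from the libraries. The median change of each list in each CLDN6 library was set among 10000 random lists of the same size, drawn from the 100 genes on each side in rank of mean level, as a description of these libraries. Members of a list share regulation, so a random list does not carry the correlation of a real one.

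The genes named were CLDN6; the 12 protein-coding genes farthest above and the 12 farthest below WT by the smaller of the changes in the CLDN6 libraries, among genes with a mean of at least 5 RPM; up to 2 members with the highest mean from each list described; and genes listed in advance, among them ESR1, PGR and other claudins. The ranking ran over all genes tested, since fewer than 6 passed the threshold. Y-linked genes and XIST were left out, and some list members that the rule names are not reported here.

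Alternatives fixed in advance were a pseudocount of 0.1, no filter on low values, filters of at least 50 reads in a library or a mean of at least 5 RPM, TMM-like, RLE and quantile scaling, the CLDN6 row left out, limma-voom on recovered reads, other correlations, ranks and fry for the lists, a 1.5-fold limit, and each CLDN6 replicate left out. Added after the data were seen were the removal of a trend with GC content, transcript length and mean level, fitted in each library with splines of 5 degrees of freedom, the same with medians aligned, protein-coding genes alone, reads thinned to the smallest depth, and the lists without CLDN6. GC content and length were known for 99.1% of genes tested. Simulated libraries without any effect, 20 sets drawn with the spread of the CLDN6 pair, gave the values that a shared WT library would then bring. Their noise was independent and of that spread in every library, WT included. The shares of genes below or above a shared control came from separate random draws of equal spread, without the genes of these data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the recovery of reads and the figures.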

Results

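RNA was sequenced from Ishikawa cells, an established human line of endometrial adenocarcinoma, in 3 libraries. In 2 libraries, CLDN6 replicates 1 and 2, the cells overexpressed CLDN6 from a lentiviral vector; the remaining library came from untreated wild-type (WT) cells. Claudin-6 is a membrane protein of tight junctions. The series concerns its adhesion signal and estrogen receptor alpha in endometrial cancer. The comparison of CLDN6 with WT asks which genes differ between cells with added claudin-6 and untreated cells. None of the 3 libraries came from cells with an empty vector, so effects of the vector or its delivery cannot be told apart from those of CLDN6. The depths behind the values were 71088867, 65755119 and 67843384 reads in CLDN6 replicate 1, CLDN6 replicate 2 and WT. Reads were found for 22927, 20680 and 22351 genes, respectively. Levels are given as RPM, the reads of a gene scaled to a common depth by the authors, in that order of libraries, and log2 changes are on the log2(RPM + 1) scale, which understates the change of low genes. WT has no replicate, so the difference of a single gene from WT is judged with the spread of the CLDN6 pair alone. The labels do not say that the libraries came from separate cultures. The p-values of single genes thus measure only the spread between these samples, which may be technical. Those of camera with a preset correlation compare the genes of a list with other genes. They do not measure variation between libraries or cultures, however small they are.

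CLDN6 itself was read at 354 and 413 RPM in the CLDN6 libraries and at 0.236 RPM in WT. These levels rest on 25197, 27129 and 16 reads. The ratio to WT was 1503 in replicate 1, with a 95% interval of 925 to 2629 from the WT reads, and 1749 in replicate 2, with an interval of 1077 to 3061. These intervals cover counting error only. CLDN6 (ENSG00000184697) lies on chromosome 16 from 3014712 to 3020071, on the minus strand in GRCh38, and its row overlaps that of TNFRSF12A, so reads of the overlap are uncertain. CLDN6 rose by a log2 change of 8.28 ± 0.98 (SE), with adjusted p = 5.81e-13 (limma, Benjamini-Hochberg) and both CLDN6 libraries above WT. Its neighbor and close paralog CLDN9 was read at 1.94, 2.65 and 1.77 RPM. The CLDN6 call was lost with limma-voom on recovered reads (adjusted p = 0.999986) and without a filter on low values (adjusted p = 0.999964), and adjusted p under the alternatives ranged from 2.88e-21 to 0.999986.

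Among the genes other than CLDN6, the levels farthest above WT in both CLDN6 libraries included those of NRG1, which encodes the growth factor neuregulin 1, at 5.70, 10.0 and 1.67 RPM. COX7B, a subunit of cytochrome c oxidase, was at 46.1, 47.6 and 20.6 RPM. NT5E, the ectonucleotidase CD73, was at 22.9, 12.7 and 5.84 RPM, and PLAU, the urokinase plasminogen activator, at 13.6, 23.8 and 6.93 RPM. On the opposite side, the gel-forming mucin MUC5AC was at 5.09, 4.76 and 27.0 RPM, the ectonucleotidase ENTPD2 at 16.7, 16.7 and 77.1 RPM, and the transcription factor STAT6 at 7.29, 7.53 and 27.5 RPM. None of these genes passed the test.

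The receptor tyrosine kinase AXL was read at 7.55, 11.9 and 4.17 RPM, and the LIM protein FHL2 at 14.5, 19.6 and 7.89 RPM. The actin-binding protein gelsolin, encoded by GSN, was at 92.3, 86.7 and 53.4 RPM. PHLDB2 was at 6.82, 6.11 and 2.70 RPM, TUB at 13.5, 10.9 and 5.13 RPM, and EPDR1 at 13.6, 20.5 and 7.49 RPM. ABHD6, a lipase of monoacylglycerols, was at 6.27, 6.24 and 3.14 RPM. The row RP11-886H22.1, at 12.06, 12.04 and 6.28 RPM, overlaps ACAA2, SNHG22 and MYO5B and is uncertain for that reason, as are PHLDB2 (overlapping PLCXD2), PLAU (C10orf55) and GSN (RAB14).

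Among genes below WT in both CLDN6 libraries, the placental-type alkaline phosphatase ALPPL2 was read at 2.62, 17.8 and 71.7 RPM, and the actin-associated protein gene SYNPO at 13.6, 6.07 and 51.9 RPM. PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, was at 56.5, 49.6 and 132.5 RPM. The retinol carrier RBP4 was at 8.07, 6.42 and 20.1 RPM, and ITIH5 at 13.2, 5.05 and 34.9 RPM. RIMS4 was at 26.8, 20.9 and 63.4 RPM, LGALS3BP at 9.28, 3.09 and 21.6 RPM, SLC38A8 at 12.4, 5.69 and 28.2 RPM, and the netrin receptor UNC5B at 7.44, 2.57 and 17.4 RPM. ALPPL2 shares sequence with ALPP, and MUC5AC with MUC5B, so their split of reads is uncertain. The rows of STAT6 and RBP4 overlap those of NAB2, LRP1 and FFAR4.

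**Figure D1:**
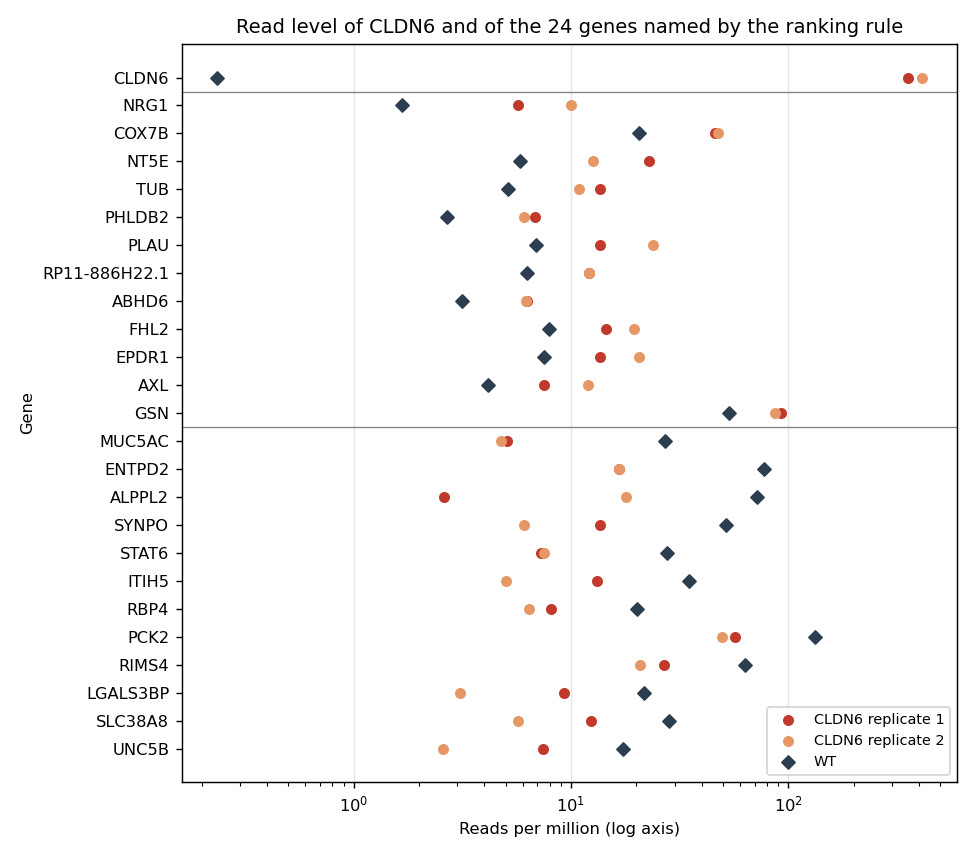
RPM on a log axis for CLDN6 and for the 24 genes chosen by the ranking rule, with CLDN6 replicates 1 and 2 as circles and WT as diamonds, 1 point per library. CLDN6 lies at 354 and 413 RPM against 0.236 RPM in WT. In the 24 genes the CLDN6 libraries lie on the same side of WT because the ranking rule selects for it.

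Among the genes named in advance for estrogen signaling, ESR1, which encodes estrogen receptor alpha, was read at 99.8, 17.2 and 71.7 RPM, so that WT lay between the CLDN6 libraries. PGR, the progesterone receptor gene, was at 7.74, 0.137 and 1.53 RPM. GREB1 was at 9.97, 4.70 and 10.5 RPM, CTSD at 272, 340 and 310 RPM, CCND1 at 647, 296 and 357 RPM, MYC at 57.9, 77.0 and 75.5 RPM, and IGFBP4 at 2.08, 1.02 and 2.56 RPM. TFF1 had 0 reads in all 3 libraries, which allows up to 0.0422, 0.0456 and 0.0442 RPM, so it was not detectable at this depth. SGK1 was at 4.37, 6.57 and 2.64 RPM, AKT1 at 116, 166 and 186 RPM, and SRC at 15.5, 22.5 and 19.3 RPM. Among the claudins and cadherins, CLDN1 was at 40.1, 37.0 and 26.3 RPM, CLDN3 at 35.6, 26.6 and 40.2 RPM, CLDN4 at 145, 48.2 and 138 RPM, CLDN7 at 102, 175 and 141 RPM, and CDH1 at 293, 116 and 235 RPM. VIM, the gene of the mesenchymal filament vimentin, had 0 reads in both CLDN6 libraries and 9 reads in WT. In the rows of CTSD, AKT1 and CLDN7, reads are shared with overlapping genes and are uncertain.

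CLDN6 was the only gene of 14509 to pass the test (limma, Benjamini-Hochberg), and 4 genes had an unadjusted p under 0.05, namely CLDN6, ALPPL2, SYNPO and ENTPD2. The log2 changes were -3.14 ± 1.18 (SE) for ALPPL2, -2.38 ± 1.17 for SYNPO and -2.14 ± 1.08 for ENTPD2, each with adjusted p = 0.99996 (limma, Benjamini-Hochberg). With the CLDN6 row left out, limma called 0 genes, with 3 at an unadjusted p under 0.05, and limma-voom on recovered reads called 0 genes, with 8 at an unadjusted p under 0.05. In data simulated with the spread of the CLDN6 pair for 14509 genes, the test called 0% of genes changed 2-fold, 2% of those changed 4-fold and 54% of those changed 16-fold, with 4 false calls. The limma fit gave every gene of a given level nearly the same spread, so the closeness of the CLDN6 replicates at a gene such as ENTPD2 did not enter its p.

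At least 2-fold above WT in both CLDN6 libraries were 5 genes. Besides CLDN6, NRG1 and COX7B, these were IL18, an inflammatory cytokine gene at 6.26, 2.97 and 0.914 RPM, and RP11-1002K11.1 at 2.60, 3.47 and 0.545 RPM, both named here after their values were seen. The row of IL18 overlaps SDHD and is uncertain. RP11-1002K11.1 lies on chromosome 8 from 32766125 to 32767959, next to the end of NRG1 at 32765040 and on the same strand. At least 2-fold below WT in both were 28 genes, among them MUC5AC, ENTPD2, ALPPL2, SYNPO, STAT6 and PCK2. The lists of single libraries were longer, with 971 genes above and 168 below WT in replicate 1, and 257 above and 2672 below WT in replicate 2. Independent lists of those sizes would share 17.2 genes above and 30.9 below. After removal of a trend with GC content, transcript length and mean level, 7 genes were shared above and 23 below, where independent lists would share 4.43 and 10.8, so that the sharing lay under that number before the removal and over it after. Simulated libraries without any effect, with the spread of the CLDN6 pair and a shared WT, gave 1460 and 1457 genes. Their noise was independent between libraries. The changes from WT correlated with r = 0.498 there and with r = -0.49 in these data, so those counts are no baseline for the sharing here. Part of the sharing may come from the shared WT library, which cannot be split. With a trimmed-mean (TMM-like) scaling, the genes above and below WT numbered 405 and 493 in replicate 1 and 1045 and 1176 in replicate 2.

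CLDN6 replicates 1 and 2 lay farther from each other than from WT, and genes of cilia and of sex steroid reception were among those at least 2-fold apart. FOXJ1, a transcription factor of ciliated cells, was read at 246 RPM in replicate 1, 11.1 RPM in replicate 2 and 66.1 RPM in WT (its row overlaps RNF157-AS1 and is uncertain), and ESR1 and PGR were also highest in replicate 1 and lowest in replicate 2. At least 2-fold apart between the CLDN6 libraries were 6296 of 14509 genes, with 5259 higher and 1037 lower in replicate 1. Against WT, 1139 genes were at least 2-fold apart in replicate 1 and 2929 in replicate 2. Across genes, which are not independent replicates, the log2 values correlated with r = 0.846 between the CLDN6 libraries, and with r = 0.952 and 0.942 between WT and replicates 1 and 2. The split between the CLDN6 libraries depended on the scaling, with 2754 genes higher and 3221 lower in replicate 1 under the TMM-like scaling, 2505 and 3568 under a median-ratio (RLE) scaling, and 2580 and 2591 after quantile normalization.

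WT lay between the CLDN6 libraries in 75.9% of genes, both CLDN6 libraries lay below WT in 15.1%, as for ENTPD2, and both lay above in 9.06%, as for NRG1. Random draws of equal spread, with no genes behind them, lay both below a shared control in 33.2% and both above in 33.4%, shares set by symmetry. The changes of replicates 1 and 2 from WT correlated across genes with r = -0.49, and their covariance was -0.198. In the libraries simulated with the spread of the CLDN6 pair, these were 0.498 and 0.871. After removal of the trend described next, the correlation was -0.213 and the covariance -0.0514. Genes of low GC content were higher in replicate 1 than in replicate 2, with a median log2 difference of 1.62 in the lowest decile of genes by GC content and -0.33 in the highest. Genes with long transcripts were higher in replicate 1 as well, with a median difference of -0.08 in the decile of shortest transcripts and 1.58 in that of the longest. Across genes, this difference had a Spearman correlation of -0.61 with GC content and 0.44 with transcript length, over 14372 genes with values. After removal of a fitted trend with GC content, transcript length and mean level, 4070 of 14372 genes were at least 2-fold apart between the CLDN6 libraries, 3749 higher and 321 lower in replicate 1, with a median difference of 0.55 left over all genes. With the medians of the libraries aligned as well, 2292 genes were, 1141 higher and 1151 lower. Reads of genes encoded in mitochondria made up 2.63%, 2.06% and 2.32% of the reads in listed genes.

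**Figure D2:**
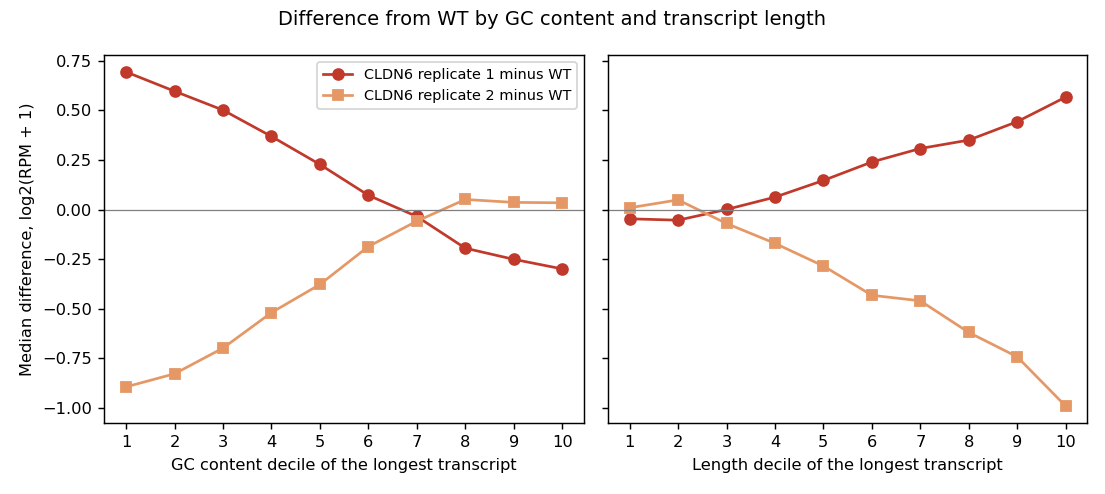
Median difference from WT in log2(RPM + 1) for genes in 10 equal groups by GC content (left) and by transcript length (right), with CLDN6 replicate 1 as circles and replicate 2 as squares. In the lowest decile by GC content the medians are 0.69 in replicate 1 and -0.89 in replicate 2.

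The gene lists fixed in advance were each compared with the other genes in CLDN6 against WT. The median of all genes lay 0.20 above WT in replicate 1 and 0.35 log2 units below it in replicate 2 (-0.35), and medians of lists are given relative to these shifts. Under camera with a preset correlation of 0.01, 12 of 35 lists passed (Benjamini-Hochberg), 4 upward and 8 downward. In 8 of the 12 the medians of both CLDN6 libraries lay on the same side of the all-gene median, and the other 4 were the lists of estrogen receptors and cofactors, adherens junctions and desmosomes, mesenchymal genes and ciliated epithelium. With a correlation estimated from these libraries, 0 of the 12 calls held and adjusted p = 0.929 with an estimated correlation for each of them. In that run and in fry, 0 lists passed and 0 had an unadjusted p under 0.05. That run and fry test each list with only the 1 residual degree of freedom, so hardly any list could pass them. The estimated correlation lay below 0.01 for YAP and TEAD targets (-0.0105), mesenchymal genes (-0.0526) and claudins (-0.0909), whose calls ended as well. It lay above 0.01 for the others that had passed. The lost calls thus decide nothing for or against the lists. Counts of members on the same side of the all-gene median in both libraries, given below, can be set beside 12.9% of all genes below it in both and 12.9% above. Random draws without any effect gave 33.2% below and 33.4% above a shared control, shares set by symmetry under independent noise of equal spread, which these data do not follow. Part of such counts may come from the shared WT library. The 12 lists that passed had the same direction under the TMM-like and RLE scalings, while the immediate early list, which did not pass, changed direction under both. On ranks, the calls of the estrogen response, claudin, endometrial epithelium and ciliated lists ended and fatty acid synthesis passed downward. At a correlation of 0.05, the p53 and endometrial epithelium calls ended, and with members of at least 5 RPM the interferon, endometrial epithelium and ciliated calls ended and NF-kappaB targets passed downward. Single members other than CLDN6 did not pass. Adjusted over the list alone, limma called 1 member, CLDN6 in the claudin list, and 0 in the other lists, with 2 members of any list, CLDN6 and ALPPL2, at an unadjusted p under 0.05 and 0 calls by limma-voom over all genes.

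Genes of the integrated stress response, which the transcription factor ATF4 drives when amino acids are short, fell as a list (camera adjusted p = 2.52e-15, Benjamini-Hochberg; adjusted p = 0.929 with an estimated correlation). Relative to all genes, their median was -0.57 in replicate 1 and -0.62 in replicate 2. Of 26 members tested, 15 lay below the all-gene median in both libraries and 0 above it in both, and 0 passed the test singly. ATF4 was read at 542, 644 and 845 RPM, and the amino acid transporter SLC7A5 at 450.04, 2002 and 1091 RPM. Named after their values were seen, asparagine synthetase (ASNS) was at 202, 182 and 357 RPM, and the pseudokinase TRIB3 at 116, 76.7 and 211 RPM. Among 10000 random lists matched on mean level, this median stood at percentile 1.96 in replicate 1 and below all of them in replicate 2.

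Genes of the G2 phase and mitosis fell as a list (camera adjusted p = 9.40e-13, Benjamini-Hochberg; adjusted p = 0.929 with an estimated correlation), with medians of -0.13 in replicate 1 and -0.73 in replicate 2. Of 30 members, 10 lay below the all-gene median in both libraries, 0 above it in both, and 0 passed singly. Among random lists the G2 and mitosis list stood at percentile 83.2 in replicate 1 and below all of them in replicate 2. Before removal of the GC and length trend it thus stood low only in replicate 2. The proliferation marker MKI67 was at 492, 99.5 and 441 RPM, and the mitotic activator CDC20 at 135, 360 and 309 RPM. The interferon response list fell as well (adjusted p = 9.01e-05 by camera, Benjamini-Hochberg; adjusted p = 0.929 with an estimated correlation), with medians of -0.16 and -0.55 over 14 members, of which 4 lay below in both libraries and 0 above in both. Among random lists the interferon list stood at percentile 5.34 in replicate 1 and 0.66 in replicate 2. STAT2 was at 53.6, 17.1 and 32.5 RPM. The p53 target list fell with medians of -0.07 and -0.41 over 23 members, 6 below and 2 above in both libraries (camera adjusted p = 0.00771, Benjamini-Hochberg; adjusted p = 0.929 with an estimated correlation), and CDKN1A, a cell cycle inhibitor, was at 166, 28.4 and 88.1 RPM and MDM2 at 157, 34.2 and 82.1 RPM. The row of MDM2 overlaps CPM and is uncertain. Among random lists the p53 target list stood at percentile 47.8 in replicate 1 and 1.68 in replicate 2, so the call rests on replicate 2.

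The estrogen response list fell (camera adjusted p = 0.00118, Benjamini-Hochberg; adjusted p = 0.929 with an estimated correlation), with medians of -0.14 in replicate 1 and -0.47 in replicate 2. Of 33 members, 9 lay below the all-gene median in both libraries, 3 above it in both, and 0 passed singly. Among random lists the estrogen response list stood at percentile 22.7 in replicate 1 and 0.04 in replicate 2. After removal of the trend its medians were 0.03 (percentile 71.2) and -0.24 (percentile 1.3), so its median was low only in replicate 2. Camera weighs means, and the list holds ALPPL2, whose log2 change was -4.33 in replicate 1 and -1.95 in replicate 2. The call ended on ranks, so it cannot be placed in a single library. CCND1, the most abundant member, is given above, and the chaperone FKBP4 was at 255, 518 and 341 RPM. The list of estrogen receptors and cofactors fell (camera adjusted p = 0.00278, Benjamini-Hochberg; adjusted p = 0.929 with an estimated correlation), yet its medians were 0.08 in replicate 1 and -0.76 in replicate 2, with 3 of 14 members below and 0 above in both libraries. Among random lists it stood at percentile 79.5 in replicate 1 and 0.02 in replicate 2, so the call rests on replicate 2. The coactivator gene CREBBP was at 111, 38.4 and 85.5 RPM. Genes of adherens junctions and desmosomes fell by the same test (camera adjusted p = 0.00496, Benjamini-Hochberg; adjusted p = 0.929 with an estimated correlation), with medians of 0.12 and -0.38 over 20 members, 4 below and 1 above in both libraries. Among random lists they stood at percentile 98.7 in replicate 1 and 0.28 in replicate 2, so the call rests on replicate 2. CTNNA1 was at 505, 306 and 491 RPM and JUP at 241, 345 and 324 RPM. Markers of endometrial epithelium fell (camera adjusted p = 0.016, Benjamini-Hochberg; adjusted p = 0.929 with an estimated correlation), with medians of -0.15 and -0.19 over 12 members, 6 below and 1 above in both libraries. Among random lists these markers stood at percentile 40.0 in replicate 1 and 10.8 in replicate 2, under percentile 2.5 in neither. After removal of the trend their medians were 0.15 (percentile 90.5) and -0.50 (percentile 0.08), on opposite sides. PAX8, whose row overlaps PAX8-AS1 and is uncertain, was at 265, 163 and 216 RPM, and EPCAM at 194, 98.5 and 125 RPM.

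Upward, targets of YAP and TEAD, the transcription factors at the end of the Hippo pathway, rose as a list (camera adjusted p = 3.89e-06, Benjamini-Hochberg; adjusted p = 0.929 with an estimated correlation). Their medians were 0.01 and 0.32, and of 20 members 7 lay above the all-gene median in both libraries and 3 below it in both. IGFBP3 was at 171, 555 and 160 RPM and CYR61 at 117, 389 and 169 RPM, and the list also holds NT5E and AXL. The mesenchymal list rose (camera adjusted p = 0.000627, Benjamini-Hochberg; adjusted p = 0.929 with an estimated correlation) with medians of -0.40 in replicate 1 and 0.74 in replicate 2 over 19 members, 3 above and 3 below in both libraries. Its percentiles were 1.46 in replicate 1 and 100 in replicate 2, so the call rests on replicate 2. Tenascin C (TNC) was at 1174, 853 and 638 RPM and transgelin (TAGLN), whose row overlaps PCSK7 and is uncertain, at 55.2, 689.97 and 146 RPM. Markers of ciliated epithelium rose (camera adjusted p = 0.00305, Benjamini-Hochberg; adjusted p = 0.929 with an estimated correlation) with medians of 1.80 in replicate 1 and -0.27 in replicate 2 over 8 members, 2 above and 1 below in both libraries. Its percentiles were 100 in replicate 1 and 9.02 in replicate 2, so the call rests on replicate 1, and TUBB4B was at 506, 1212 and 857 RPM. The claudins rose as a list (camera adjusted p = 1.95e-17, Benjamini-Hochberg; adjusted p = 0.929 with an estimated correlation) with medians of 0.03 and 0.66 over 11 members, 5 above and 3 below in both libraries. Without CLDN6 the claudin list did not pass (camera adjusted p = 0.69, Benjamini-Hochberg).

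The other 23 lists tested did not pass camera in the main setting, with a smallest adjusted p of 0.0722 (Benjamini-Hochberg). Among signaling lists, the medians in replicates 1 and 2 were 0.32 and -0.43 for SRC-family, PI3K, AKT and SGK genes, 0.39 and -0.76 for FOXO targets, and -0.44 and 0.07 for immediate early genes. They were 0.36 and 0.08 for WNT targets, 0.06 and -0.46 for NOTCH targets, and -0.02 and -0.36 for retinoic acid targets. For tight junction genes other than claudins they were 0.12 and -0.36, for keratins -0.50 and 0.71, and for E2F targets -0.04 and 0.20. Immune lists had medians of -0.12 and 0.13 for MHC genes and -0.18 and -0.05 for NF-kappaB targets. Stress lists had medians of -0.18 and -0.05 for the unfolded protein response, -0.59 and 0.37 for heat shock, and -0.35 and 0.59 for NRF2 targets. Metabolic lists had medians of 0.01 and 0.43 for hypoxia and glycolysis, -0.25 and 0.37 for cholesterol synthesis, -0.43 and -0.12 for fatty acid synthesis, and -0.41 and 0.73 for oxidative phosphorylation. Lists of library quality had medians of -0.02 and -0.01 for mitochondrially encoded genes, -0.45 and 0.66 for ribosomal proteins, 0.16 and 0.53 for histones, 0.42 and -0.05 for nuclear noncoding RNAs, and -0.26 and 0.33 for housekeeping genes. Markers of other cell types were few, with 3 genes tested each for stroma, endothelium, HEK293 and neural cells, and pluripotent cells, and 1 for leukocytes. Their medians were 0.02 and 0.42 for stroma, 0.14 and -0.05 for endothelium, 0.14 and -0.13 for HEK293 and neural cells, -0.10 and -0.74 for pluripotent cells, and -0.20 and 0.27 for leukocytes. In 10 of the 23 lists the median or the mean change had another sign than the direction of camera, which compares a list with the other genes.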

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

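The GC and length correction, the aligned medians, the protein-coding genes alone, the thinned reads and the lists without CLDN6 were chosen after seeing the data. The count of 1 gene past the threshold, which is CLDN6, became 0 without a filter on low values (146 genes at an unadjusted p under 0.05), 0 with limma-voom on recovered reads (8), and 0 without the CLDN6 row (3), where the gene called is no longer tested. The log2 change of CLDN6 was 8.28 without the filter and 10.62 with limma-voom, above WT in each setting. Without the filter its SE was 0.57, under the 0.98 of the main fit, but the prior degrees of freedom were 2.41 where the main fit had infinite ones. That call was thus lost through the prior and not through the change or its SE. With limma-voom the SE was 2.88. CLDN6 passed the threshold in the other 8 settings that tested it, and left-out replicates gave 8.17 to 8.39. The 5 genes at least 2-fold above WT in both CLDN6 libraries became 22 with a pseudocount of 0.1, 3 with a mean of at least 5 RPM and 44 at 1.5-fold, and the 28 below became 51, 18 and 147. With a replicate left out, the genes above ranged from 257 to 971 and those below from 168 to 2672, since a single library then decides. The 6296 genes at least 2-fold apart between the CLDN6 libraries became 4070 after the GC and length correction and 2292 with medians aligned as well, and ranged from 4944 to 7120 elsewhere. The 12 lists past the threshold became 0 with an estimated correlation, 0 with an estimated correlation after the GC and length correction, and 0 with fry, which tests each list alone, and 9 to 12 elsewhere, with 0 of these 12 lists reversed. On ranks, camera adjusted p (Benjamini-Hochberg) became 0.102 for estrogen response, 0.332 for claudins, 0.148 for endometrial epithelium and 0.186 for ciliated epithelium, and 0.0321 for fatty acid synthesis, which passed only there. At a correlation of 0.05 it became 0.0605 for p53 targets and 0.0595 for endometrial epithelium. With members of at least 5 RPM it became 0.12 for interferon, 0.413 for endometrial epithelium and 0.513 for ciliated epithelium, and 0.0294 for NF-kappaB targets, which passed only there. The cause of these changes was not tested. The 0 calls with an estimated correlation and with fry come from tests with only 1 residual degree of freedom, so they decide nothing for or against the lists. Of 40 named genes other than CLDN6, none passed in any setting, and up to 6 changed sign, without CLDN6 replicate 1. Tests of edgeR and DESeq2 were not run, by a choice made because the deposited values are on a log2 scale, although the recovered reads would have allowed them. Tests of transcripts were not run, since rows are genes. Leaving out a replicate leaves no residual degree of freedom, so no count of calls exists there. No paired analysis was possible because the groups share fewer than 2 replicate numbers and the WT title carries none. With 1 WT library, the size of a change that can be called depended on the spread of the CLDN6 pair in the simulations, and the part of depth was not tested.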

Other observations

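All genes and tests in this part were chosen after their values were seen, apart from the lists, which were fixed in advance. Several genes of motile cilia were read mostly in CLDN6 replicate 1. PIFO was at 39.3 RPM in replicate 1, 0.73 RPM in replicate 2 and 2.03 RPM in WT, TPPP3 at 25.01, 0.35 and 1.93 RPM, RSPH1 at 5.82, 0.0456 and 0.398 RPM, and the dynein heavy chain DNAH5 at 4.90, 0.304 and 0.354 RPM. After the GC and length correction, the median of the ciliated list relative to all genes was 1.53 in replicate 1 and -0.13 in replicate 2, and the difference between the replicates lay above that of all 10000 random lists. TXNIP, a gene induced by glucose, was at 87.6, 6.01 and 6.32 RPM, and FN1 and COL5A1 were at 113, 8.23 and 24.1 RPM and at 15.4, 0.076 and 3.42 RPM. The actin gene ACTA2 was at 12.2, 73.2 and 18.7 RPM, and ANKRD1 at 1.65, 37.2 and 2.37 RPM. CTGF was at 7.08, 37.9 and 5.98 RPM and THBS1 at 19.6, 76.2 and 33.0 RPM. The rows of RSPH1 and ACTA2 overlap SLC37A1 and FAS and are uncertain.

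Several further genes lay below WT in both CLDN6 libraries by at least 2-fold, although the test did not call them. The mucin gene MUC5B was at 1.25, 1.08 and 8.96 RPM, the receptor gene TNFRSF14 at 0.549, 0.852 and 6.10 RPM, and the retinol transporter STRA6 at 0.535, 1.95 and 8.65 RPM. The glycine transporter SLC6A9 was at 26.8, 18.6 and 55.4 RPM, and the cytoskeletal adaptor PDLIM1 at 63.6, 52.4 and 129.8 RPM. The rows of TNFRSF14 and SLC6A9 overlap RP3-395M20.8 and CCDC24 and are uncertain. After the GC and length correction, 3 lists stood under percentile 2.5 of random lists in both CLDN6 libraries, namely the integrated stress response, G2 and mitosis, and interferon lists. Before this correction only the integrated stress response list did, and in replicate 1 the G2 and mitosis list stood at percentile 83.2 and the interferon list at 5.34. At the opposite end, 1 list stood as high in both, that of YAP and TEAD targets, at percentiles 99.6 and 99.3 with corrected medians of 0.23 and 0.34 relative to all genes, but at percentiles 64.0 and 92.3 before the correction.

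The CLDN6 libraries were at least 2-fold apart at 6296 of 14509 genes, with WT between them at most genes. A label swapped between the groups is argued against, since CLDN6 stood above WT in both libraries labelled CLDN6, with 925 as the lower end of the 95% interval of the lower ratio. Reads thinned to the smallest library left 6298 such genes, but the depths were so close that thinning does not test depth. The trend with GC content and transcript length was fitted with separate splines and the longest transcript, and other forms were not tested. After its removal with medians aligned, 2292 of 14372 genes stayed at least 2-fold apart, 1141 higher and 1151 lower in replicate 1. A trend of the form fitted is thus argued against as the whole cause. It may still be part of the cause, since GC content and length fitted 43.4% of the variance of the difference, and library preparation, RNA quality and culture stay open, with no biological explanation tested, since both libraries carry the same label.

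The split of the libraries by group gave 1 gene past the threshold, and the highest of the other splits, with CLDN6 replicate 2 set apart, gave 2160, while the split with replicate 1 set apart gave 137, so that all 3 of the 3 splits gave at least 1 gene. These 3 splits are too few for a share under 0.05. The 2160 genes point to a structure of the libraries that the groups do not follow, though that split takes its spread from replicate 1 and WT, the closest pair, and so largely restates their closeness. WT lay between the CLDN6 libraries in 75.9% of genes, so this split does not show whether replicate 2 stands apart or WT lies in the middle.

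The integrated stress response list lay lower than other genes in both CLDN6 libraries. A trend with GC content and transcript length, in the form fitted here, is argued against as the whole cause. After its removal the list lay at -0.27 in replicate 1 and -0.77 in replicate 2 relative to all genes, below all 10000 random lists in each. Before removal its median in replicate 1 was -0.57 relative to all genes, so part of that shift went with the trend. Against WT itself, the medians after removal were -0.08 and -1.13. Random lists do not carry the correlation of a real one, so these percentiles only describe these libraries. The series has 1 WT library and none with an empty vector. A WT culture that was short of amino acids, the lentiviral vector and CLDN6 overexpression itself therefore cannot be told apart as sources of the difference. A lower ATF4 program due to CLDN6 is only a candidate among these, a hypothesis that more WT libraries and libraries with an empty vector could test. The call by camera did not hold with an estimated correlation, a run with only 1 residual degree of freedom, in which hardly any list could pass.

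The list of G2 and mitosis genes lay lower by camera, mostly in CLDN6 replicate 2, a call that did not hold with an estimated correlation (adjusted p = 0.929 with an estimated correlation, Benjamini-Hochberg). A trend with GC content and transcript length, in the form fitted here, is argued against as the whole cause. After its removal the list lay, relative to all genes, at -0.20 in replicate 1 (percentile 0.07) and -0.70 in replicate 2, below all 10000 random lists. Here too, random lists do not carry the correlation of a real one. Before removal, the list in replicate 1 stood at percentile 83.2 of random lists, so whether replicate 2 alone or both libraries carry the difference cannot be told apart.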
